A study of Homo sapiens with 14 samples.

How the data were processed

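Total RNA from 14 samples was profiled on Illumina BeadChips. Per the labels' protocols, RNA was extracted with Trizol, cleaned up and treated with DNase I on RNeasy columns, checked on a Bioanalyzer and converted to biotinylated cRNA with the Ambion TotalPrep kit. The deposited table without normalization holds, per the file headers, an average signal intensity and a detection p-value for 47323 probes on each array. The deposited signal runs from -18.7 to 20915, so the values are linear and already had background subtracted. The deposited detection p-values move in steps of 1 over 770, the number of negative controls this implies. A further deposited table holds the authors' processed intensity values, linear and quantile normalized over the 14 arrays, with column medians of 5.77 to 5.82. Each array's ranks there matched its own signal (Spearman correlation 1, at most 0.919 with any other array). The upstream software and the genome build behind the probe annotation are not given in the sources used here.

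Signals were background corrected with the normexp method of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, then quantile normalized over all 14 arrays and log2 transformed. Probes with a detection p under 0.01 on every array of at least 1 of the 6 groups were kept, 19225 in number. A single linear model with 1 mean per group was fitted (8 residual degrees of freedom, prior degrees of freedom 6.78), with empirical Bayes moderation and an intensity trend. p-values are those of limma's moderated test, two-sided, adjusted by Benjamini and Hochberg over all probes kept, with a threshold of 0.05. The contrasts were ONC201 against DMSO in HCT116, parental RKO and R1, R1 against parental RKO under each treatment, and the differences of the ONC201 effect between R1 and parental RKO and between parental RKO and HCT116.

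The annotation table covers 30121 probes, of which 30113 have 1 gene symbol and 8 several, and 17202 probes have none. Entrez identifiers of 30074 matched the RefSeq gene table (assembly GRCh38.p14), used for names and gene order, and 0 symbols were updated. Each gene is represented by its kept probe with the highest mean signal, which gave 11335 genes from 15265 kept probes with 1 symbol. Genes with another kept probe past the threshold in the opposite direction are said to disagree. Where no array of the dimmer group was above background, the change is given as "at least" the fold between the brighter group's mean and the lowest signal that counted as detected on the dimmer group's arrays. For a difference of effects, a gene that was not above background on any array of 1 of the 4 groups is given with its direction and adjusted p only.

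Gene lists, 26 in number, cover the integrated stress response, serine, glycine and folate metabolism, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, the death receptor pathway, inhibitors of apoptosis, the BCL2 family, p53 targets, G1/S and G2/M genes, cholesterol synthesis, respiratory chain subunits, mitochondrial chaperones and proteases, glycolysis and hypoxia, FOXO targets, ERK pathway output, the interferon response, heat shock, NRF2 targets, ribosomal proteins, dopamine receptors, drug efflux transporters, colon epithelial differentiation, mesenchymal genes, and fibroblast and blood cell markers. Lists with at least 5 measured members, 22 of them, were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with a correlation estimated from the data. Genes called in HCT116 with a log2 change of at least 0.58 were followed in the RKO lines as sets. Named genes are the 10 highest and 10 lowest changes past the threshold whose groups do not overlap, the 8 highest and 8 lowest for the differences of effects, up to 4 members with the smallest adjusted p per list, and ATF4, DDIT3, TNFRSF10B, TNFSF10, XIAP, CLPP and DRD2. Contrasts, lists, named-gene rules and alternatives were chosen before the data were examined.

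The alternatives were the authors' values, no background correction, median scaling, no detection filter, detection on all arrays, moderation without trend or robust, array weights, the mean of a gene's probes, each chip alone, only the groups of a contrast in the fit, a minimum log2 change of 1, other limits for the HCT116 sets, and leaving out each array. Between 33.0% and 39.6% of probes were detected on an array. The median within-group SD on the log2 scale was 0.153 and 0.165 in HCT116, 0.0991 and 0.0924 in parental RKO and 0.118 and 0.0832 in R1 (DMSO and ONC201). The fit was tested on simulated data with 200 of the 19225 probes changed: at log2 1 it called 99.5% of them for HCT116, 92% for parental RKO and 87.5% for R1. For the differences of effects it called 42% (R1 minus parental RKO) and 59.5% (RKO minus HCT116) at log2 1. At log2 0.58 it called 0% for both differences. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.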

Results

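The series measured gene expression in human colon cancer cells treated with ONC201, a small molecule also called TIC10 in the labels, at 10 µM, or with its solvent DMSO. HCT116 cells, described as p53-null, made up 6 arrays with 3 per treatment. Their p53 status was not checked on these arrays. RKO cells made up 4 arrays with 2 per treatment, and R1, an RKO line with acquired resistance to ONC201, another 4 with 2 per treatment. The design text counts 6 samples of wild-type RKO, whereas 4 parental RKO arrays were analysed here. The labels do not give the exposure time. They also do not say that replicates came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Between 15611 and 18717 of the 47323 probes were above background on an array, and the number of arrays limits the precision. Arrays of a group correlated at 0.988 to 0.996. The HCT116 arrays lay on 1 chip and the RKO and R1 arrays on another, so differences between HCT116 and RKO cannot be told apart from differences between chips. In each line the DMSO arrays took earlier chip positions than the ONC201 arrays, and parental RKO took earlier positions than R1. Effects of treatment, and differences between R1 and parental RKO, therefore cannot be told apart from position on the chip by the layout. Values after ± are standard errors of the model on the log2 scale.

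In HCT116 cells, the question was which transcripts change with ONC201 in cells described as p53-null. The series title points to ATF4 and to TNFRSF10B, the death receptor DR5. Genes of the ATF4 and CHOP stress response were among those that rose most. PCK2, a mitochondrial gluconeogenic enzyme, rose 7.99-fold (adjusted p = 4.87e-11) and DDIT3, which encodes the stress transcription factor CHOP, 7.98-fold (adjusted p = 4.7e-09). UPP1, a uridine phosphorylase, rose 7.66-fold (log2 2.94 ± 0.16). The glutathione-degrading enzyme gene CHAC1 rose by 2.65 ± 0.17, the pseudokinase gene TRIB3 by 2.57 ± 0.16 and NIBAN1 by 2.22 ± 0.12. SPRR2D, an epithelial envelope protein gene, had the highest change at 9.44-fold, and BEGAIN (2.84 ± 0.24) and the cytokine receptor gene IL20RB (2.39 ± 0.12) rose as well. Of the 3 DMSO arrays, CHAC1 and SPRR2D were above background on 1. SESN2, a stress-induced regulator of mTORC1, rose at least 4.53-fold (limma, Benjamini-Hochberg adjusted p = 2.56e-08), since it was not above background in DMSO. ATF4 itself rose 1.80-fold (log2 0.85 ± 0.08, adjusted p = 9.87e-06) and TNFRSF10B 2.88-fold (1.53 ± 0.12, adjusted p = 6.62e-07). Their other probes differed in size: 1.65 (adjusted p = 6.28e-08) and 0.15 (adjusted p = 0.569) for ATF4, 1.89 (adjusted p = 0.000458) and 0.50 (adjusted p = 0.0727, above background on 2 of 3 DMSO arrays) for TNFRSF10B.

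The lowest changes in HCT116 were those of the vitamin D hydroxylase gene CYP24A1, 3.04-fold lower (-1.60 ± 0.14), and the transcription factor gene MYB, 2.71-fold lower (-1.44 ± 0.14). TMSB15B, LRRC26, ZCCHC12, the carbonic anhydrase gene CA2 and S1PR5 fell between 2.33-fold and 2.39-fold, and MCM4, part of the replicative helicase, 2.31-fold. TMSB15B and TMSB15A, which also fell (2.27-fold), are near-identical copies whose probes may share signal. In all, 997 genes rose and 870 fell among 11335 tested, 107 and 24 of them at least 2-fold. XIAP, an inhibitor of caspases named in the series title, changed by 0.02 ± 0.17 (adjusted p = 0.953) and CLPP, the mitochondrial protease described as a target of ONC201, by -0.08 ± 0.13 (adjusted p = 0.736). TNFSF10, which encodes TRAIL, and DRD2, a dopamine receptor described as another target, were not above background on any of the 14 arrays.

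Of the 26 measured members of the integrated stress response list, 23 rose in HCT116, 0 fell and 3 did not pass, with 25 rising when adjusted over the list alone and a median of 1.46 (camera, adjusted p = 9.93e-37). Besides the genes above, the secreted factor gene GDF15 (1.87 ± 0.09) and the mTORC1 inhibitor gene DDIT4 (1.71 ± 0.09) rose. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, rose in 11 of 18 cases and fell in 0 (11 adjusted over the list alone; adjusted p = 3.39e-08), led by SARS1 (1.36 ± 0.10) and GARS1 (1.08 ± 0.08). In serine, glycine and folate metabolism, 4 of 9 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.000247). PSAT1 rose by 1.92 ± 0.10 and MTHFD2 by 1.21 ± 0.10. Of 16 targets of NRF2, the oxidative stress regulator, 6 rose and 0 fell (7 adjusted over the list alone; adjusted p = 7.1e-05), among them SRXN1 (1.10 ± 0.08) and HMOX1 (0.99 ± 0.10). ERK pathway output genes rose in 10 of 17 cases with 0 lower (10 and 1 adjusted over the list alone; adjusted p = 1.44e-05), led by the phosphatase gene DUSP5 (1.17 ± 0.08). Nuclear-encoded respiratory chain subunits fell in 8 of 45 cases with 0 higher (10 lower adjusted over the list alone; adjusted p = 0.00015), such as ATP5F1A (-0.27) and COX7B (-0.49).

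Replication genes fell in HCT116. Of 29 G1/S and DNA replication genes, 23 fell and 0 rose (25 adjusted over the list alone; median -0.60, adjusted p = 3.72e-18), including GINS2 (-1.14 ± 0.10) and UHRF1 (-1.01 ± 0.10). Of 28 G2/M and mitosis genes, 10 fell and 0 rose (13 adjusted over the list alone; median -0.29, adjusted p = 3.46e-06). Heat shock genes fell in 6 of 13 cases with 0 higher (11 lower adjusted over the list alone; adjusted p = 8.97e-07), including the chaperone gene HSPA1B (-0.87 ± 0.12). Among 22 p53 targets, 7 rose and 0 fell (7 and 2 adjusted over the list alone), with a median of -0.02 and an adjusted p = 0.0648 for higher values. GDF15 and TNFRSF10B stand in this list and in the stress list, and CDKN1A, the p21 gene, rose by 0.97 ± 0.15. The other CDKN1A probe lay near background, at means of 4.66 with DMSO and 4.80 with ONC201. It was above background on 0 of 3 DMSO arrays and 1 of 3 ONC201 arrays. Of 14 BCL2 family genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), a call lost at an adjusted p = 0.0831 with an estimated correlation. Cytosolic ribosomal proteins (6 of 33 higher, 0 lower, 6 adjusted over the list alone) had an adjusted p = 0.0717 with an estimated correlation. Drug efflux transporters (1 of 6 higher, 0 lower, 2 adjusted over the list alone) had an adjusted p = 0.0883 with an estimated correlation. The number of genes called fell to 897 when each chip was normalized and fitted alone and to 904 when only the HCT116 arrays were in the fit. HCT116 arrays had the wider spread within groups, so the spread shared over all arrays may give too many calls here.

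In parental RKO cells, replication genes were among the lowest changes with ONC201. The replication factor gene GINS2 fell 5.23-fold (log2 -2.39 ± 0.13), RRM2, a subunit of ribonucleotide reductase, 4.83-fold (-2.27 ± 0.12), the dUTPase gene DUT 4.40-fold (-2.14 ± 0.14), MYB 4.25-fold (-2.09 ± 0.17) and the chromatin remodeller gene HELLS 4.14-fold (-2.05 ± 0.19). The autophagy gene MAP1LC3C had the lowest change, 8.77-fold lower (-3.13 ± 0.20). The histone gene H2BC9 (-2.27 ± 0.14), PTMA (-2.25 ± 0.29), the splicing factor gene SRSF3 (-2.15 ± 0.22) and MRPL57 (-2.12 ± 0.32) fell too. Histone genes and PTMA have near-identical copies, so the source of those signals is uncertain. The defensin gene DEFB103A, which has a near-identical copy, rose at least 19.3-fold (limma, adjusted p = 6.08e-11), TMEM71 at least 5.52-fold (adjusted p = 1.04e-09). The semaphorin receptor gene NRP1 rose at least 4.03-fold (adjusted p = 8.14e-08) and SLC67A1 at least 4.38-fold (adjusted p = 2.64e-07), none of these 4 genes being above background in DMSO. ANKRD1 rose 8.84-fold (3.14 ± 0.15), LAMP3, a lysosomal membrane protein gene, 7.77-fold (2.96 ± 0.14), the collagen-modifying enzyme gene PLOD2 7.76-fold (2.96 ± 0.16), GDF15 5.41-fold (2.44 ± 0.10), ZNF79 5.14-fold and the ubiquitin ligase gene RBCK1 5.03-fold. PLOD2 was above background on 1 of 2 DMSO arrays, and MRPL57 and XIAP on 1 of 2 ONC201 arrays. Over all genes, 1945 rose and 1769 fell, 317 and 378 at least 2-fold. With median scaling 2423 rose and 1672 fell, the median of all genes moving to 0.13.

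All but 1 of the 29 G1/S and DNA replication genes fell in parental RKO, 28 in number, with 0 higher (28 adjusted over the list alone; median -1.34, camera adjusted p = 9.43e-25), among them MCM3 (-1.73 ± 0.10) and TYMS (-1.92 ± 0.11). Of 28 G2/M genes, 22 fell and 0 rose (24 adjusted over the list alone; median -0.86, adjusted p = 6.54e-14), including CCNA2 (-1.38 ± 0.12) and PLK1 (-1.71 ± 0.16). Of 22 p53 targets, 12 rose, 0 fell and 10 did not pass (12 adjusted over the list alone; median 0.47, adjusted p = 0.00037), with TP53INP1 at 1.37 ± 0.15, AEN at 1.06 ± 0.15 and RRM2B at 1.22 ± 0.18. In the stress response list, 13 of 26 rose and 3 fell (13 and 3 adjusted over the list alone; median 0.34, adjusted p = 0.0553). DDIT3 rose 2.84-fold (adjusted p = 1.58e-05). PPP1R15A, which recruits the eIF2α phosphatase, rose by 1.11 ± 0.11 and TNFRSF10B by 0.60 ± 0.14 (adjusted p = 0.00519). Other TNFRSF10B probes did not pass, at 0.85 (limma adjusted p = 0.0757) and 0.27 (limma adjusted p = 0.392). The members that fell, named after their values were seen, were CHAC1 (-1.51), the amino acid transporter gene SLC38A2 (-1.51 ± 0.18) and DDIT4 (-0.76). ATF4 changed by -0.04 ± 0.10 (adjusted p = 0.844), XIAP by -0.02 ± 0.21 (adjusted p = 0.959) and CLPP by 0.08 ± 0.15 (adjusted p = 0.758).

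Other lists in parental RKO held members moving both ways. Heat shock genes fell in 6 of 13 cases and rose in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0996 with an estimated correlation), with HSP90AB1 at -0.90 ± 0.11. Probes of HSP90AA1 passed in opposite directions. In the endoplasmic reticulum chaperone list, 4 of 18 rose and 7 fell (4 and 7 adjusted over the list alone), such as DNAJB9 (1.08 ± 0.19, higher) and PDIA4 (1.99-fold lower). In glycolysis and hypoxia response, 2 of 24 rose and 8 fell (3 and 8 adjusted over the list alone; adjusted p = 0.0559), such as LDHA (-1.05) and ALDOA (-0.92). Of 15 FOXO targets, 7 rose and 3 fell (7 and 4 adjusted over the list alone; adjusted p = 0.25), led by GADD45A (0.92 ± 0.11). In the death receptor pathway, 3 of 9 rose and 2 fell (3 and 2 adjusted over the list alone). TNFRSF10D, a decoy receptor of TRAIL, rose by 1.28 ± 0.23 and TRADD by 0.76 ± 0.15, while BID fell by 0.52 with another of its probes passing in the opposite direction. BIRC5, the survivin gene, fell by 1.11 and DIABLO, an antagonist of inhibitors of apoptosis, rose by 0.49 ± 0.10. Without RKO DMSO replicate 1 the count of called genes was 2301 and without RKO ONC201 replicate 2 it was 2356, against 3714 with all arrays.

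**Figure D1:**
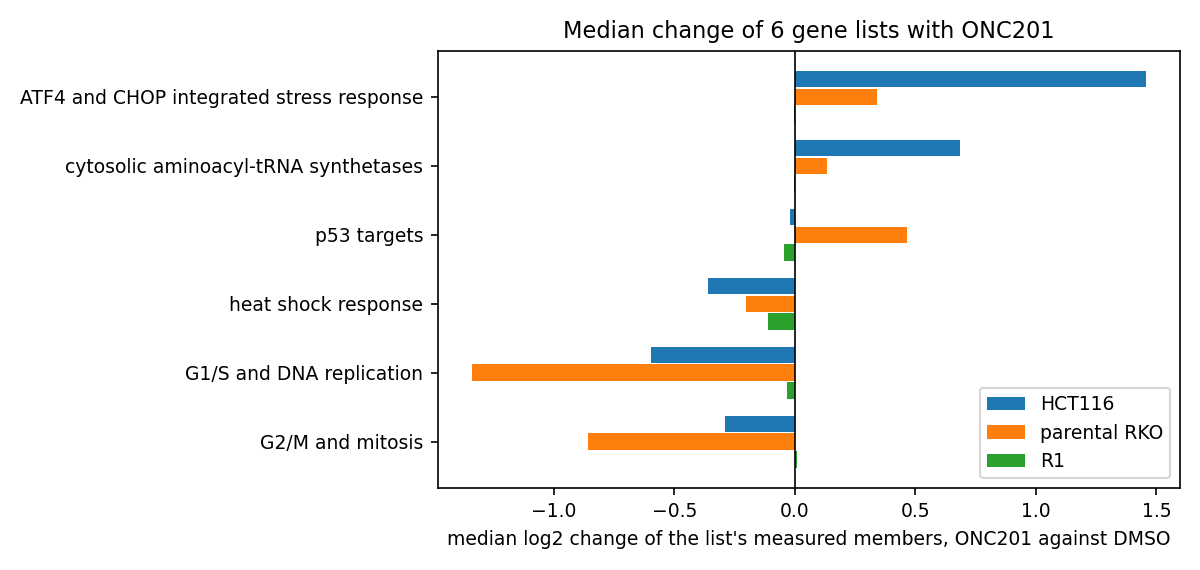
Median log2 change with ONC201 against DMSO over the measured members of 6 gene lists, as bars for HCT116, parental RKO and R1. The stress response list has its highest median in HCT116 (1.46), the replication list its lowest in parental RKO (-1.34), and the R1 medians lie between -0.11 and 0.01.

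The effect of ONC201 was compared between parental RKO and HCT116 as a difference of changes within each chip. It differed for 1667 genes, 819 with a higher value in RKO and 848 with a lower value. With median scaling the balance turned, to 1193 higher and 763 lower, with the median of all genes at 0.11. The stress list differed most: 19 of 26 members had a lower change in RKO and 1 a higher change (21 and 1 adjusted over the list alone; median -1.24, adjusted p = 1.1e-16). CHAC1, above background on 1 of 3 HCT116 DMSO arrays, differed by -4.16 ± 0.27, DDIT4 by -2.48 ± 0.14, PCK2 by -2.28 ± 0.14 and UPP1 by -2.51 ± 0.25. SESN2 also had a lower change in RKO (adjusted p = 3.66e-06), without a size since it was not above background in HCT116 under DMSO. Under DMSO, the mean signal of every stress member except SLC38A2, GDF15, KLHL24 and STC2 was higher in parental RKO than in HCT116. TRIB3 stood at 11.69 against 8.90 and ASNS at 12.77 against 10.89. The lower changes in RKO therefore cannot be told apart from a higher starting level, itself not separable from the chip. Serine, glycine and folate genes (0 of 9 higher, 5 lower; 6 lower adjusted over the list alone; median -0.85) and aminoacyl-tRNA synthetases (0 of 18 higher, 6 lower; 1 and 8 adjusted over the list alone; median -0.38) also had lower changes in RKO. So did 18 of 29 replication genes (20 adjusted over the list alone; median -0.78) and 14 of 28 G2/M genes (20 adjusted over the list alone; median -0.58). ERK pathway output had 5 of 17 members lower (5 adjusted over the list alone; median -0.42) and the NRF2 list 5 of 16 (5 adjusted over the list alone; median -0.24), with 0 higher in each of these 4 lists. The glycolysis and hypoxia call (1 of 24 higher, 5 lower; 1 and 8 adjusted over the list alone; median -0.28) had an adjusted p = 0.272 with an estimated correlation. For p53 targets, 8 of 22 had a higher change in RKO and 1 a lower change (11 and 3 adjusted over the list alone; median 0.49; adjusted p = 0.0566 with an estimated correlation), with AEN at 1.10 ± 0.19 and PPM1D at 0.93 ± 0.19. PLOD2, above background on 1 of 2 RKO DMSO arrays, differed by 3.12 ± 0.21. DEFB103A (adjusted p = 3.46e-09), TMEM71 (adjusted p = 5.09e-08) and ANKRD1 (adjusted p = 2.46e-07) had a higher change in RKO, without a size since none was above background in HCT116. Both lines also overlapped: 449 genes rose in both against 171 for independent lists, 429 fell in both against 136, and 84 passed in opposite directions. The correlation of the changes across genes was 0.42, genes not being independent replicates. Left-out arrays moved this count to 837 without RKO DMSO replicate 1, 1052 without RKO DMSO replicate 2 and 920 without RKO ONC201 replicate 2.

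In R1 cells, the question was whether ONC201 still changes expression. No gene passed: 0 rose and 0 fell by limma at the adjusted threshold, and the smallest adjusted p was 0.343. An unadjusted p under 0.05 was found for 312 genes (2.75% of those tested), a smaller share than that threshold gives with no effect. The shared spread may be too wide for R1, with a median within-group SD of 0.118 and 0.0832 against 0.153 and 0.165 in HCT116. Fitting its chip alone or only the R1 groups also called 0 genes. With the authors' processed values 9 genes passed, and with no background correction 10. DDIT3 changed by 0.30 ± 0.17, TNFRSF10B by -0.04 ± 0.14, ATF4 by -0.02 ± 0.10, XIAP by 0.45 ± 0.21 and CLPP by 0.03 ± 0.15 (n = 2 arrays per treatment; limma adjusted p = 1 for each). GINS2, RRM2 and the rest of the 29 replication genes had a median of -0.03, the stress list a median of -0.00 and p53 targets -0.04. None of the 22 lists tested was called, the lowest camera adjusted p being 0.0729 for heat shock genes (median -0.11). Simulated data took the spread shared over all arrays, including the wider spread of HCT116, and not that of the R1 arrays alone. There the same fit called 87.5% of 200 probes changed by log2 1 in the R1 contrast. It called 8.5% of 200 probes changed by log2 0.58.

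The genes called in HCT116 with a log2 change of at least 0.58 gave sets chosen by the HCT116 contrast, with normalization and spread shared over the 14 arrays. In parental RKO, the 444 higher genes had a median change of 0.35 with 75.2% in the same direction (camera p = 1e-12; p = 0.00358 with an estimated correlation). The 280 lower genes had a median of -0.56 with 79.6% in the same direction (camera p = 1.36e-19; p = 1.49e-06 with an estimated correlation). In R1 the medians were 0.01 (55.2% in the same direction, camera p = 0.346, 0.606 with an estimated correlation) and -0.00 (50.7%, camera p = 0.295, 0.185 with an estimated correlation). The difference of the ONC201 effect, R1 minus parental RKO, had medians of -0.32 (camera p = 1.28e-12, 0.00368 with an estimated correlation) and 0.51 (camera p = 2.45e-19, 1.58e-06 with an estimated correlation).

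**Figure D2:**
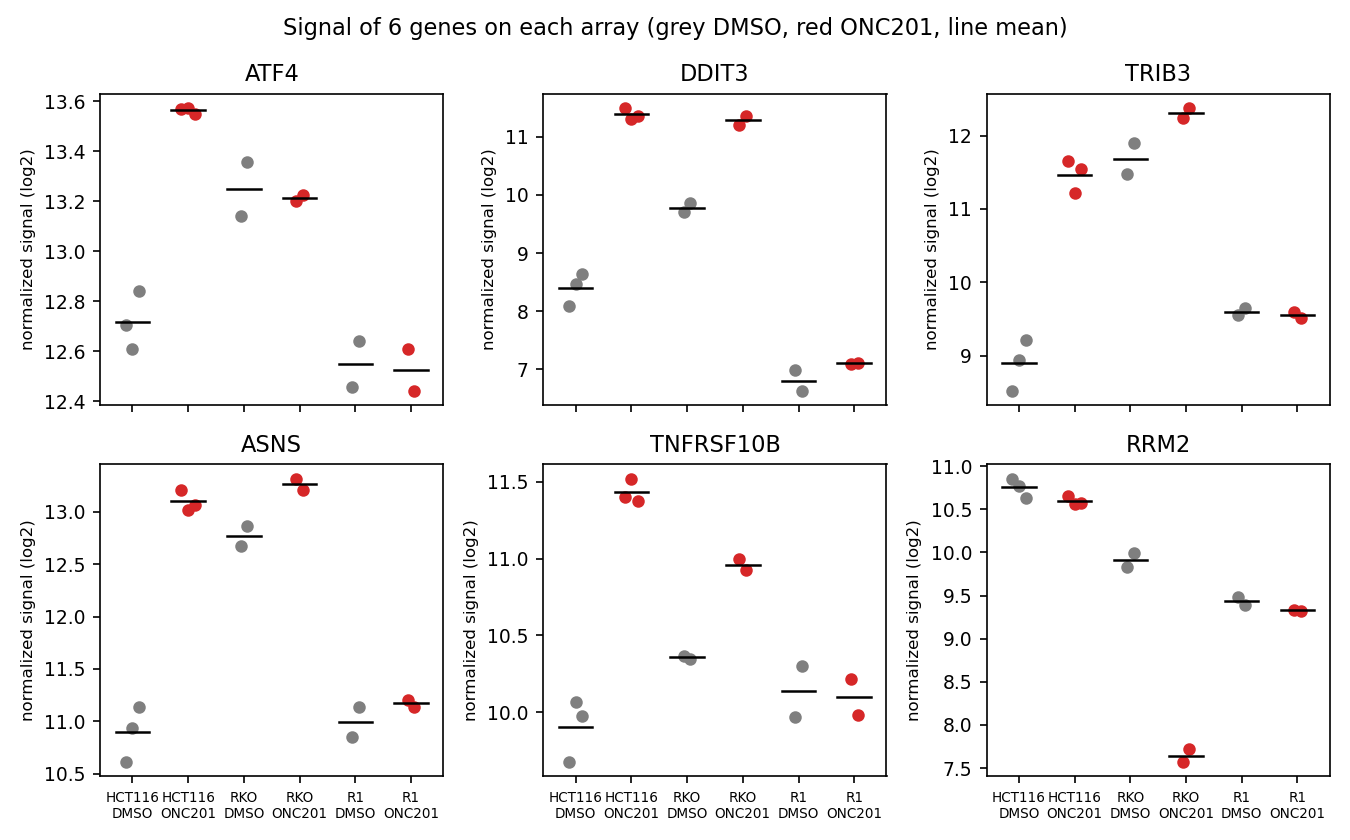
Normalized log2 signal of 6 genes on each of the 14 arrays, by cell line and treatment, with a line at each group's mean and separate vertical axes per gene. DDIT3 rises with ONC201 from a mean of 8.40 to 11.39 in HCT116 and from 9.78 to 11.28 in parental RKO, while its R1 means are 6.80 and 7.10.

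The test of the difference itself found 1659 genes whose ONC201 effect differed between R1 and parental RKO, 811 with a higher value in R1 and 848 with a lower value. With median scaling these were 787 and 1049, with the median of all genes at -0.12, and with the authors' values 765 and 673. Of 29 replication genes, 28 had a higher change in R1 and 0 a lower change (28 adjusted over the list alone; median 1.31, camera adjusted p = 1.74e-27), with GINS2 at 2.39 ± 0.18 and RRM2 at 2.16 ± 0.16. Of 28 G2/M genes, 19 were higher and 0 lower (22 adjusted over the list alone; median 0.82), and of 22 p53 targets 0 were higher and 8 lower (10 lower adjusted over the list alone; median -0.48, adjusted p = 2.62e-05). GDF15 differed by -2.49 ± 0.15, DDIT3 by -1.21 ± 0.24 (adjusted p = 0.00422) and TNFRSF10B by -0.64 ± 0.20 (adjusted p = 0.0483), its other 2 probes not passing: 1 stood at -0.42 (adjusted p = 0.654) and 1, not above background in R1 under ONC201, was also lower (adjusted p = 0.244). PTMA (2.74 ± 0.41), MAP1LC3C (2.67 ± 0.28), H2BC9 (2.44 ± 0.20) and NUF2 (2.18 ± 0.38) were among the highest differences. MAP1LC3C was already lower in untreated R1 than in parental RKO, so its difference cannot be told apart from that lower level. LAMP3 had a lower change in R1 (-2.89 ± 0.20). So did DEFB103A (adjusted p = 4.12e-09), ANKRD1 (adjusted p = 2.78e-07), TMEM71 (adjusted p = 1.54e-07) and PLOD2 (adjusted p = 4.52e-06), without a size since none was above background in R1. In the stress list 3 of 26 members had a higher and 8 a lower change in R1 (3 and 10 adjusted over the list alone; median -0.18, adjusted p = 0.0674). The call for glycolysis and hypoxia (8 of 24 higher, 2 lower; 8 and 2 adjusted over the list alone) had an adjusted p = 0.343 with an estimated correlation. The TNFRSF10B, MAP1LC3C and H2BC9 differences did not pass with the authors' values or without background correction, and that of TNFRSF10B also not with median scaling or without the intensity trend. The count was 855 without RKO DMSO replicate 1, 1103 and 986 without RKO ONC201 replicates 1 and 2, and 966 and 856 without R1 ONC201 replicates 1 and 2.

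Untreated R1 and parental RKO cells differed in 1102 genes, 501 higher and 601 lower in R1, 85 and 141 at least 2-fold. With median scaling the balance turned, to 650 higher and 616 lower. Stress response genes were among the lowest in R1. DDIT4 was 10.7-fold lower (log2 -3.42 ± 0.11), DDIT3 7.86-fold lower (-2.98 ± 0.17) and CHAC1 at least 4.89-fold lower (limma adjusted p = 1.43e-07). The scavenger receptor gene CD163L1 (22.8-fold), the decoy receptor gene IL13RA2 (15.4-fold), MAP1LC3C (10.4-fold), the elongation factor gene ELL2 (10.3-fold), TBC1D23 (8.99-fold) and ERRFI1, an inhibitor of EGFR signalling (7.52-fold), were lower. The cholesterol exporter gene ABCA1 was at least 4.51-fold lower (adjusted p = 7.23e-09). Higher in R1 were the embryonic globin gene HBE1 (at least 35.7-fold, adjusted p = 1.26e-12), the fetal globin gene HBG1, which has a near-identical copy (at least 4.27-fold, adjusted p = 7.73e-08), OPCML (at least 13.4-fold, adjusted p = 1.08e-11) and the cubilin gene CUBN (at least 6.34-fold, adjusted p = 2.17e-09). TGM2, a transglutaminase, was 36.0-fold higher (5.17 ± 0.17), the urokinase gene PLAU 10.1-fold (3.33 ± 0.13), the hyaluronan synthase gene HAS2 9.47-fold, BNC2 6.71-fold, CALB2 6.28-fold and MAPKAP1 6.06-fold. XIAP differed by -0.17 ± 0.21, CLPP by 0.16 ± 0.15 and TNFRSF10B by -0.22 ± 0.14, none past the threshold, and ATF4 was 1.62-fold lower (-0.70 ± 0.10, adjusted p = 0.000471), its other probes standing at -1.16 (adjusted p = 2.16e-05) and 0.21 (adjusted p = 0.605).

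Of the 26 stress list members, 22 were lower in untreated R1, 0 higher and 4 not past the test (22 adjusted over the list alone; median -1.09, camera adjusted p = 2.31e-30), including GDF15 (-2.08 ± 0.10) and SESN2 (-2.64 ± 0.16). Serine, glycine and folate genes were lower in 4 of 9 cases with 0 higher (5 lower adjusted over the list alone), such as PSPH (-1.78 ± 0.17) and PSAT1 (-1.24 ± 0.12). Of 18 aminoacyl-tRNA synthetases, 7 were lower with 0 higher (10 lower adjusted over the list alone). FOXO targets (5 of 15 lower, 0 higher; 9 lower adjusted over the list alone) and ERK pathway output (5 of 17 lower, 0 higher; 5 lower adjusted over the list alone) were lower. GADD45A stood at -1.36 ± 0.11, IER3 at -2.62 ± 0.11 and EGR1 at -1.86 ± 0.14. Heat shock genes were higher in 7 of 13 cases with 0 lower (8 higher adjusted over the list alone; adjusted p = 2.17e-06), such as HSPA1B (1.33 ± 0.15). Cholesterol synthesis genes were higher in 2 of 18 cases and lower in 0 (6 higher adjusted over the list alone; median 0.27, adjusted p = 0.00131), with HMGCS1 at 0.75 ± 0.13. NRF2 targets were higher in 6 of 16 cases with 1 lower (6 and 1 adjusted over the list alone; adjusted p = 0.012): GCLM stood at 1.09 ± 0.16 and SLC7A11 at least 2.03-fold lower. In the colon epithelial list, 0 of 8 were higher and 3 lower (3 adjusted over the list alone; adjusted p = 0.126 with an estimated correlation): EPCAM was lower by log2 -2.38, CLDN3 was at least 2.35-fold and KRT8 at least 1.89-fold lower. PMAIP1, which encodes NOXA, was lower by -1.56 ± 0.16, and MVP, the major vault protein gene, higher by 1.40 ± 0.16. Leaving out RKO DMSO replicate 1 or 2 gave 548 and 494 called genes, leaving out R1 DMSO replicate 1 or 2 gave 600 and 673, and a fit of these 4 arrays alone gave 721.

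G2/M genes were higher in 5 of 28 cases and lower in 0 in untreated R1 (6 higher adjusted over the list alone; median 0.23, camera adjusted p = 0.000151). G1/S genes were higher in 0 of 29 cases and lower in 3 (3 adjusted over the list alone; median -0.070, adjusted p = 0.067). AURKA (1.10 ± 0.11), UBE2C (0.72 ± 0.09) and TPX2 (0.65 ± 0.13), 3 of the G2/M genes that passed, lie on chromosome 20, as does TGM2. Over 296 measured protein-coding genes of that chromosome the median difference was 0.41 with 84.8% of genes higher in R1, and in the ONC201 arrays, which share no array with the DMSO comparison, it was 0.32 with 77.4% higher. The chromosome was singled out after these values were seen.

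**Figure D3:**
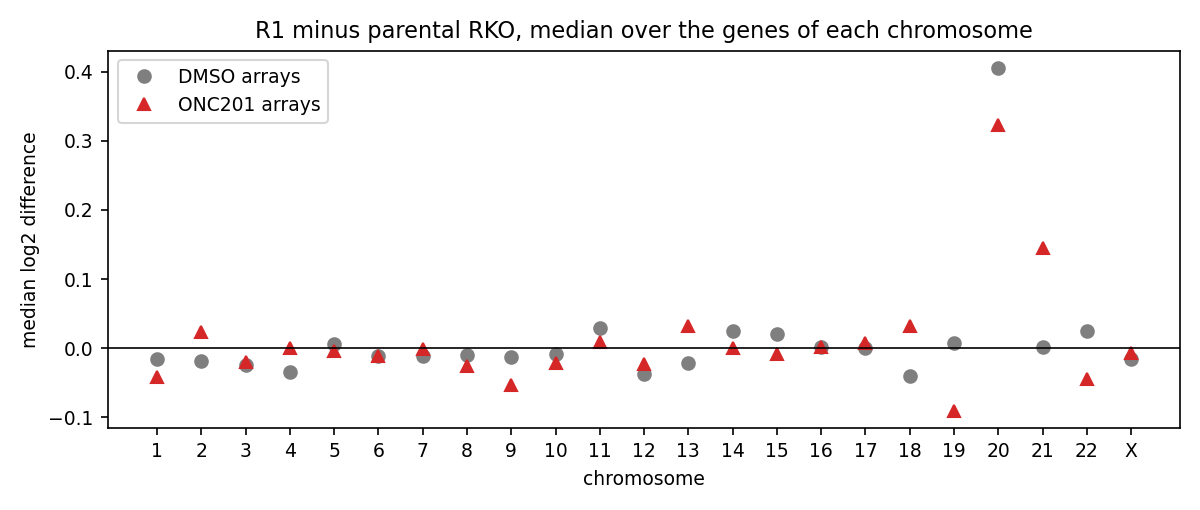
Median log2 difference, R1 minus parental RKO, over the measured protein-coding genes of each chromosome, with circles for the DMSO arrays and triangles for the ONC201 arrays. Chromosome 20 stands at 0.41 and 0.32, and every other chromosome lies between -0.04 and 0.03 in the DMSO arrays, with chromosome 21 at 0.15 in the ONC201 arrays.

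With ONC201 in both lines, R1 differed from parental RKO in 4234 genes, 2041 higher and 2193 lower, 490 and 559 at least 2-fold. Of the 1102 genes that differed under DMSO, 954 (86.6%) had the same direction here, 758 passed again in that direction and 40 passed in the opposite direction. Stress genes were lower in 22 of 26 cases and higher in 1 (23 and 1 adjusted over the list alone; median -1.64, camera adjusted p = 7.33e-17), GDF15 by -4.57 ± 0.10 and DDIT3 by -4.18 ± 0.17. TNFRSF10B was lower by -0.86 ± 0.14 (adjusted p = 0.000281). Its other probes did not pass. One stood at -0.72 (limma adjusted p = 0.121), and another, not above background in R1 under ONC201, was also lower (limma adjusted p = 0.0812). Replication genes were higher in 27 of 29 cases with 0 lower (27 adjusted over the list alone; median 1.18) and G2/M genes in 27 of 28 with 0 lower (27 adjusted over the list alone; median 1.13). Of 22 p53 targets, 15 were lower and 0 higher (15 and 1 adjusted over the list alone; median -0.57, adjusted p = 2.98e-05). Among 13 heat shock genes, 11 were higher and 0 lower (11 adjusted over the list alone; median 0.74). Cholesterol synthesis genes were higher in 10 of 18 cases and lower in 1 (11 and 2 adjusted over the list alone). Serine, glycine and folate genes, ERK pathway output and NRF2 targets, all called under DMSO, were not called with ONC201. Over the alternatives their camera adjusted p ran from 0.0317 to 0.184, from 0.045 to 0.267 and from 0.0317 to 0.172. FOXO targets were lower in 8 of 15 and higher in 2 (9 and 2 adjusted over the list alone), and aminoacyl-tRNA synthetases lower in 10 of 18 and higher in 1 (10 and 1 adjusted over the list alone), the latter call lost with median scaling (adjusted p = 0.0724; from 0.000273 over the alternatives). The glycolysis and hypoxia call (11 of 24 higher, 4 lower; 12 and 4 adjusted over the list alone) was lost at an adjusted p = 0.177 with an estimated correlation. That for colon epithelial genes (0 of 8 higher, 4 lower; 4 adjusted over the list alone) was lost at an adjusted p = 0.0721 with an estimated correlation.

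Some lists were not called in any comparison. The death receptor list (1 of 9 higher and 1 lower in HCT116), the inhibitors of apoptosis (1 of 9 lower and 0 higher in HCT116, 1 of each in parental RKO), mitochondrial chaperones and proteases (2 of 18 higher and 2 lower in HCT116, 3 and 2 in parental RKO) had no camera call. Neither had interferon response genes (2 of 20 higher and 1 lower in HCT116, 4 and 6 in parental RKO, and 5 and 2 in R1 against parental RKO under ONC201, where the list passed without a detection filter, adjusted p = 0.0455, up to 0.21 over the alternatives) or the endoplasmic reticulum chaperones (5 of 18 higher and 3 lower in HCT116). Adjusted over the list alone, these HCT116 counts were 1 and 1, 0 and 1, 2 and 2, 2 and 1, and 5 and 3 higher and lower. Lists with fewer than 5 measured members had counts only. In untreated R1 against parental RKO, 0 of 4 mesenchymal genes, 0 of 2 fibroblast and stroma markers and 0 of 4 blood and immune markers differed (1 mesenchymal gene higher adjusted over the list alone). In HCT116, CD68 rose by 0.74 ± 0.10 among the blood and immune markers, and DRD4 was the only measured dopamine receptor, at 0.18 ± 0.18 (adjusted p = 0.564).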

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

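The tests of noise in the R1 arrays, of exchanged arrays, of a residual response, of normalization in the stress list and of dividing cells were chosen only after the result was seen. The limits for 2 of them, the residual response and dividing cells, were also loosened after their values were seen. By the limits first written, both explanations would have been counted against. Noisier R1 arrays, which stayed open by the limit of their own test, are counted against from the test of hidden noise, also after the values were seen.

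The effect of ONC201 differed between R1 and parental RKO, by limma's test of the difference itself, for 1659 genes. The list medians that differed, R1 minus parental, were -0.48 for p53 targets, 1.31 for G1/S and DNA replication, 0.82 for G2/M and mitosis and 0.17 for glycolysis and hypoxia, the last lost at an adjusted p = 0.343 with an estimated correlation. Among single genes, PTMA (2.74), MAP1LC3C (2.67), H2BC9 (2.44), GINS2 (2.39) and NUF2 (2.18) had a higher change in R1, and LAMP3 (-2.89), DDIT3 (-1.21) and TNFRSF10B (-0.64, its other 2 probes not passing) a lower change. DEFB103A (adjusted p = 4.12e-09), ANKRD1 (adjusted p = 2.78e-07), TMEM71 (adjusted p = 1.54e-07) and PLOD2 (adjusted p = 4.52e-06) also had a lower change, without a size since none was above background in R1. The sets called in HCT116 differed by -0.32 for the higher genes and 0.51 for the lower genes. MAP1LC3C was already lower in untreated R1, so its difference cannot be told apart from that lower level.

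Between parental RKO and HCT116 the same kind of test found 1667 genes, and here cell line, chip and any difference of exposure time cannot be told apart. Nor can the lower changes of stress genes in RKO be told apart from their mostly higher signal there under DMSO. The list medians, RKO minus HCT116, were -1.24 for the integrated stress response, -0.85 for serine, glycine and folate metabolism, -0.38 for aminoacyl-tRNA synthetases, 0.49 for p53 targets, -0.78 for G1/S and DNA replication, -0.58 for G2/M and mitosis, -0.28 for glycolysis and hypoxia, -0.42 for ERK pathway output and -0.24 for NRF2 targets. With an estimated correlation, p53 targets had an adjusted p = 0.0566 and glycolysis and hypoxia an adjusted p = 0.272. PLOD2 (3.12) and ZNF79 (2.59) had a higher change in RKO. CHAC1 (-4.16), MAP1LC3C (-3.13), UPP1 (-2.51), DDIT3 (-1.49), TNFRSF10B (-0.92) and ATF4 (-0.88) had a lower change. The other 2 TNFRSF10B probes did not pass (adjusted p = 0.141 and 0.643), and those of ATF4 stood at -1.65 (adjusted p = 2.51e-05) and 0.25 (adjusted p = 0.547). Of the genes above, CHAC1 was above background on 1 of 3 HCT116 DMSO arrays, MAP1LC3C on 1 of 3 in each HCT116 group and PLOD2 on 1 of 2 RKO DMSO arrays. Without a size, since a group was not above background, DEFB103A (adjusted p = 3.46e-09), TMEM71 (adjusted p = 5.09e-08) and ANKRD1 (adjusted p = 2.46e-07) had a higher change, and SPRR2D (adjusted p = 2.46e-07) and SESN2 (adjusted p = 3.66e-06) a lower change.

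For the absence of called genes in R1, noisier R1 arrays (within-group SD 1.05 times that of parental RKO) hiding a response of the parental size are counted against, since noise adds to the spread and the SD of the R1 changes across genes was 0.316 times that in parental RKO. Also counted against are exchanged R1 arrays, since the mean of the HCT116-higher genes ranged over the 4 R1 arrays by 0.0634 times the parental difference. R1 cells labelled ONC201 without drug action cannot be told apart from a lost response, since both leave the HCT116-higher genes unshifted (camera p = 0.346 at an inter-gene correlation of 0.01). The R1 and parental effects correlated across genes at 0.20 (0.078 with the authors' values), and the R1 effect correlated at 0.196 with later minus earlier parental arrays. The parental effect was not compared with that difference, so whether position on the chip accounts for the agreement stays open. A small residual response stays open. With camera at an inter-gene correlation of 0.01, the parental-higher genes had p = 0.000762 in R1 and the parental-lower genes p = 0.00581. With an estimated correlation camera gave p = 0.138 and p = 0.0155. The same direction as in parental RKO was seen for 64.9% and 56.4% of these genes, with R1 medians of 0.049 and -0.024. The HCT116-higher genes would shift by only 0.026 at that size, against 0.011 observed. Acquired resistance, which the labels name, also stays open as a hypothesis.

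For the lower stress genes in untreated R1, normalization is counted against, since the list median was -1.11 or further from 0 under the other scalings. Among these, the authors' values and no background correction are near-identical. Stress in the parental DMSO cultures alone cannot be told apart: the R1 minus parental difference under ONC201 plus the HCT116 effect had a median of -0.10, and only 3 members were uncalled in HCT116. More dividing cells in R1 also cannot be told apart, with G1/S genes at a median of -0.070 and G2/M genes at 0.23. A lower stress response kept in R1 as part of its acquired resistance stays a hypothesis that these arrays do not test, with 20 members lower under both treatments.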

How the results depend on the processing

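No named gene or list result called in either setting reversed under the alternatives run for it. Named genes were run with the authors' values, no background correction, median scaling, no intensity trend and left-out arrays. Lists were run with these, no detection filter, the mean of probes and an estimated correlation. The authors' values and no background correction gave nearly the same numbers (1535 genes in HCT116 with each), so they are not separate checks. The counts of kept calls below include both. The balance of higher and lower genes turned in some alternatives. With median scaling it turned for R1 against parental RKO under DMSO (650 and 616) and for RKO minus HCT116 (1193 and 763). For the latter it also turned with array weights (1213 and 1142). For R1 minus parental RKO it turned with the authors' values (765 and 673), no background correction (766 and 674), no detection filter (576 and 541) and detection on all arrays (742 and 685). For R1 against parental RKO under ONC201 it turned with detection on all arrays (1762 and 1758). A 2-fold limit turned it in parental RKO (317 and 378) and for R1 minus parental RKO (323 and 286), and leaving out single arrays turned it for the 2 differences of effects, so no weight is put on these balances. Requiring a 2-fold change left 131 genes in HCT116, 695 in parental RKO, 226 and 1049 for R1 against parental RKO under DMSO and ONC201, and 609 and 481 for the differences R1 minus parental RKO and RKO minus HCT116; the added limit is the cause. For HCT116, each chip alone gave 897 and only its groups in the fit 904, and for R1 against parental RKO under DMSO only its groups gave 721. The same 2 alternatives gave more genes elsewhere: 4301 and 4187 in parental RKO, 2249 and 2219 for R1 minus parental RKO and 4869 and 5114 for R1 against parental RKO under ONC201. Each chip alone gave 1443 under DMSO, and RKO minus HCT116 gave 1357 with only its groups. The fit used here shares the spread over all arrays. The median within-group SD was 0.153 and 0.165 in HCT116, against 0.0832 to 0.118 in the RKO and R1 groups. A shared spread may thus give too many calls in HCT116 and too few in RKO. The 721 under DMSO goes the other way, and the cause was not tested. In R1, the authors' values gave 9 genes and no background correction 10, against 0 otherwise; the cause was not tested. Leaving out each array gave 1295 to 1787 genes in HCT116, 2301 to 2747 in parental RKO, 0 in R1, 494 to 673 and 2871 to 3134 for R1 against parental RKO under DMSO and ONC201, 855 to 1215 for R1 minus parental RKO and 837 to 1801 for RKO minus HCT116, where a lone array is assumed to vary like the other groups. Leaving out arrays, named genes kept their call in 2646 cases, lost it in 418 and gained one in 16, and lists in 274, 16 and 7. Among the other alternatives, named genes kept it in 1948 cases, lost it in 112 and gained one in 20, and lists in 323, 20 and 25. For lists, moderation without trend left the camera test unchanged, so its calls count as kept without being a check. The integrated stress response list in parental RKO passed, at a fixed correlation of 0.01, with the authors' values (median 0.44, adjusted p = 0.0185), without background correction, without a detection filter, with the mean of probes and without RKO DMSO replicate 2; the cause was not tested. Over its alternatives the adjusted p ran from 0.00535 to 0.39, the latter with an estimated correlation on the values used here. Its difference R1 minus parental RKO also passed in some, from 0.0176 to 0.362. The list calls lost on leaving out an array were those for drug efflux transporters, the BCL2 family and ribosomal proteins in HCT116, glycolysis and hypoxia in both differences and p53 targets in RKO minus HCT116, each also lost with an estimated correlation. Median scaling moved the median of all genes to 0.13 in parental RKO, -0.12 for R1 minus parental RKO and 0.11 for RKO minus HCT116. Fitting each chip alone gives no value for RKO minus HCT116. No paired analysis was possible because the labels pair no treated array with a control. Genes near background limit what can be seen, since at most 39.6% of probes were detected.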

Other observations

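The tests of normalization and of the state of the parental DMSO cultures for chromosome 20 were chosen only after the result was seen.

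Without treatment, DDIT3 (adjusted p = 1.73e-08), TRIB3 (adjusted p = 6.04e-06) and ASNS (adjusted p = 1.36e-06) were lower in R1 than in parental RKO. The mean log2 signal of DDIT3 under DMSO was 8.40 in HCT116, 9.78 in parental RKO and 6.80 in R1, that of TRIB3 8.90, 11.69 and 9.60, and that of the asparagine synthetase gene ASNS 10.89, 12.77 and 10.99. HCT116 lay on another chip, so its level cannot be compared without that difference.

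In R1 against parental RKO, genes of chromosome 20 differed together: the median over 296 genes was 0.41 in the DMSO arrays, with 103 genes called higher and 4 lower, while the largest chromosome median over shuffled orders was 0.11. For means of 20 neighbouring genes, each log2 difference was capped at 1 in size. The largest such mean, 0.61 from PXMP4 to ERGIC3, lay at percentile 100 of 1000 shuffled orders and was 0.46 in the ONC201 arrays. All 10 separate windows above the shuffled limit lay on this chromosome. Normalization is counted against, since the median was 0.446 with median scaling. It was 0.454 with the authors' values and without background correction, which are near-identical. The state of the parental DMSO cultures is also counted against, since the median was 0.32 in the ONC201 arrays. A gained copy of the chromosome in R1, or in a cell from which it grew, is a hypothesis that may account for the shift. A lost copy in the parental cultures would give the same sign, so the difference does not show which line changed. DNA was not measured. Of the 5 G2/M genes called higher, 3 lie there; the other 25 members, 2 of them called, had a median of 0.20 (camera p = 0.0201 with an estimated correlation, not adjusted over lists).

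The 6 HCT116 arrays can be split into 3 and 3 in 10 ways, and 1 of them, the real split, called 1867 genes, against at most 0 for any other. 10 splits are too few for a share under 0.05. Every other split mixes both treatments in each group, so an effect of ONC201 adds to the spread and lowers the calls. Their lack of calls therefore does not measure what unrelated groups would give.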
